A study of Rattus norvegicus with 18 samples.

How the data were processed

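Total RNA of 18 INS1E samples was hybridised, 150 ng each, to Affymetrix rat gene arrays, 1 sample per array and 3 arrays in each of 6 groups, per the labels. The deposited values are log2 signals, normalised by the authors. The submitters' processing notes name RMA and Partek without a role or order, and their settings are not given in the sources used here. The log2 values were tested as deposited. The table attached to the series held 17017 probe sets, and the series matrix held 29214, with identical values for the shared ones. Every probe set in the attached table reached at least 5.00 on some array, but 1113 of the 12197 others did so too, so the rule that selected them stays unknown.

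Gene names came from the attached table. Of its probe sets, 14698 carried 1 gene symbol, 2306 carried none and 13 carried a symbol turned into a date, and none of the last kind was named. There were 13136 distinct symbols, of which 11287 were current symbols in the RefSeq table of the rat assembly GRCr8, used for names alone, 1021 were older names and 828 were not matched, and the file's own names were kept. For a gene with several probe sets, that with the highest mean was used. Genes in the lowest 25% of mean signal were left out, which left 9852 tested.

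Groups came from the sample labels. One limma model (limma 3.58.1 in R 4.3.3, lmFit and eBayes) of all 6 groups gave every comparison, so that all shared 12 residual degrees of freedom, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The 14 comparisons were glucose against none within each pretreatment, each vitamin D form against none and against the other in each glucose state, the same 3 contrasts averaged over glucose states, and the interaction of each form with glucose. These, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The glucose effect averaged over pretreatments, and every fit that left out all 6 arrays with the same number, were added after seeing the data, once the 14 comparisons had given 0 genes.

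The 19 gene lists covered vitamin D response, vitamin D metabolism and transport, immediate early, carbohydrate response (ChREBP), beta-cell identity and hormone, secretion and ion channel, calcium and cAMP responsive, unfolded protein response, amino acid response (ATF4), sterol synthesis, glycolysis, oxidative phosphorylation, cell cycle, oxidative stress (NRF2), inflammatory (NF-kB), p53 and apoptosis, circadian clock and ribosomal protein genes, and markers of other cell types. Members below the filter on low values were not tested, and the counts of list members are of tested genes. Some genes belong to more than 1 list. Nr4a1 is in the immediate early and the calcium and cAMP lists, and Per1 is in the latter and the clock list. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Whether a list held or was lost was judged from the latter. Fry was also run, and its results are not reported here. Named genes were, per comparison, the 8 highest and 8 lowest among those that passed, up to 3 members of each list with the smallest adjusted p, the 4 with the smallest p where none passed, and in every comparison Cyp24a1, Vdr, Ins1, Ins2, Txnip, Fos and Egr1 where measured. LOC, RGD and numbered predicted genes were passed over and the next gene was taken. Some genes that the rule picked were left out of the text.

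The labels number the arrays of each group 1 to 3. Whether the numbers pair samples was checked from the correlation of same-numbered arrays' deviations from their group means. In 8 of the 9 comparisons between groups of 3 every such correlation was above 0.1, and in the calcidiol effect without glucose the lowest was 0.0533. The pairing comes from these values and not from the labels. The main model had no block, and the fit with the replicate number as a block was an alternative.

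Other alternatives were no filter and a stricter filter on low values, the series matrix, quantile normalisation, median centring of each array, the mean of a gene's probe sets, every probe set tested, an intensity trend with robust estimation, no moderation, array weights, a fit of the compared groups alone, and leaving out each array in turn. The scripts were tested on simulated data of 9852 genes with 200 changed. For the glucose effect without vitamin D, 97.0% of changes of 1 log2 unit and 75.6% of changes of 0.5 were recovered, and for the glucose effect averaged over pretreatments 99.6% and 93.6%. For the calcitriol effect without glucose 96.6% and 78.4% were recovered, and for the calcitriol interaction with glucose 91.6% and 48.2%. With the 12 arrays numbered 1 and 2 the recovered shares were 94.6% and 51.4%, 98.8% and 87.6%, 92.4% and 50.2%, and 78.8% and 18.8%, in the same order. All these shares hold for the simulated spread only, and not for genes whose arrays disagree within a group. Over all arrays Txnip differed by 1.36 (SE 0.55) after glucose without vitamin D and was not called. The median half-width of the 95% intervals in that comparison was 0.19. A count of 0 genes therefore does not exclude changes of 1 log2 unit.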

Results

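Gene expression was measured in INS1E cells, an insulin-secreting line derived from a rat insulinoma, on 18 Affymetrix rat gene arrays, 1 per sample. The samples formed 6 groups of 3. Before stimulation the cells had been kept for 72 h with 10 nM calcidiol, with 10 nM calcitriol or with neither. Calcidiol is the circulating, mono-hydroxylated form of vitamin D, and calcitriol is the hormonally active form, which carries a further hydroxyl group at carbon 1. The labels give 11 mM glucose in the culture of all 6 groups. After 60 min in a buffer free of glucose, 1 group of each pretreatment received 22 mM glucose for 60 min and the other did not. Neither state therefore matches the culture glucose. The median log2 signal per array lay between 7.52 and 7.63, and the number of arrays limits the precision. The labels do not say that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Of the genes required in each comparison, Cyp24a1 was not analysed here, and Fos lay below the filter on low values.

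The arrays numbered 3 stood apart from those numbered 1 and 2. Txnip, which encodes a thioredoxin-binding protein whose transcription follows glucose metabolism, had a log2 signal of 12.29 and 12.22 on the arrays labelled glucose 1 and 2 but 10.33 on the array labelled glucose 3. On the array labelled calcitriol 3, which had no glucose stimulation by its label, Txnip was 12.11, against 10.48 and 10.46 on the arrays labelled calcitriol 1 and 2. On the array labelled calcidiol with glucose 3 it was 10.23. Casr, the gene of the calcium-sensing receptor, was 9.52 and 9.55 on the calcidiol arrays numbered 3, without and with glucose, and 6.20 to 6.48 on the calcidiol arrays numbered 1 and 2. All labels were kept as given, and each count of genes called over all tested is printed for the 18 arrays and, where it differed, for the 12 arrays numbered 1 and 2, an alternative chosen after seeing the data. The camera tests are given for the 18 arrays. Leaving out the arrays numbered 1, or those numbered 2, gave 0 genes in every comparison by limma.

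**Figure D1:**
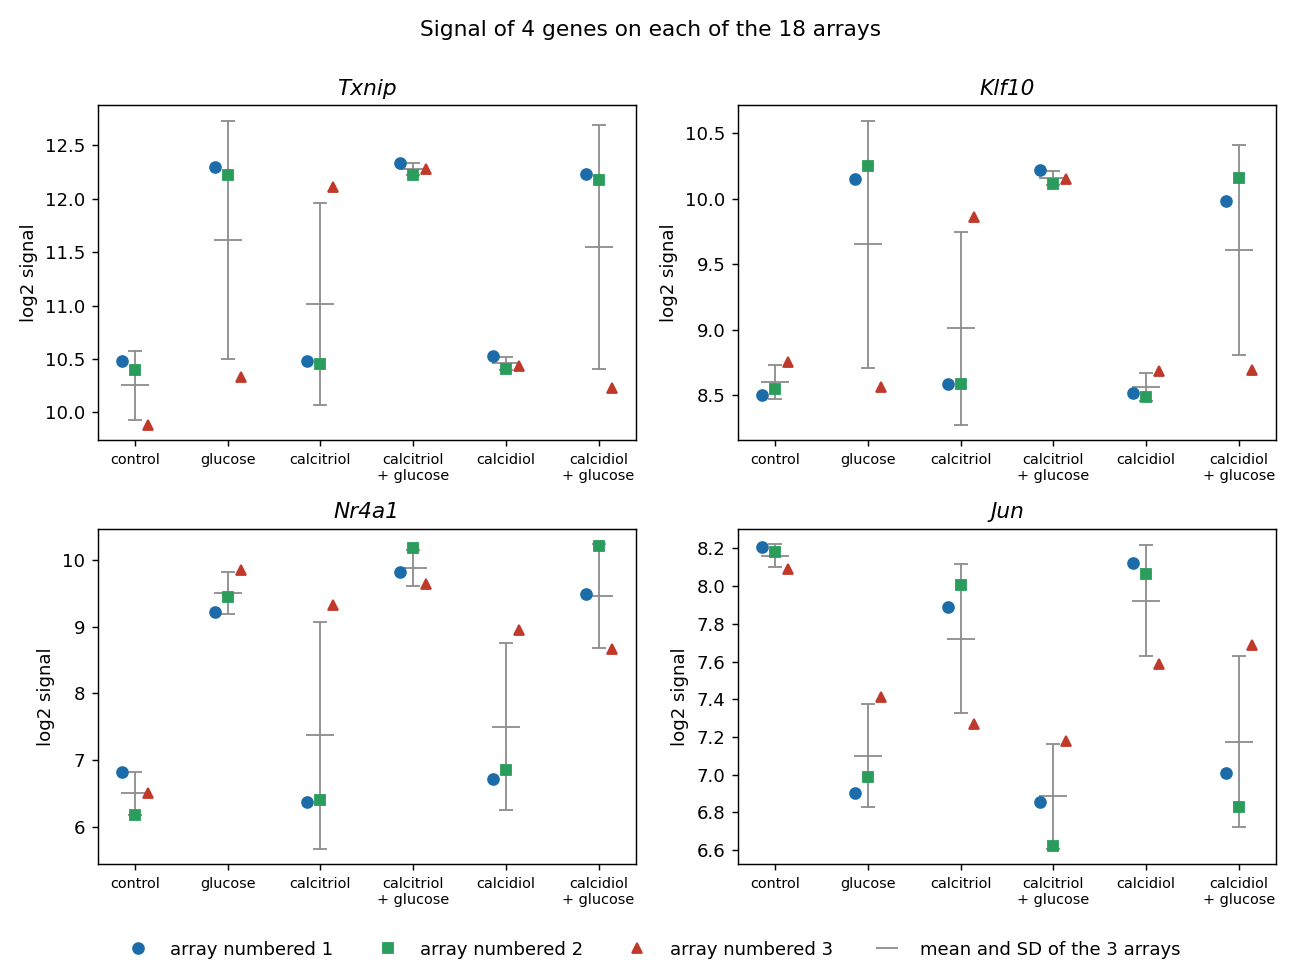
Log2 signal (vertical axes) of Txnip, Klf10, Nr4a1 and Jun on each of the 18 arrays, by group (horizontal axes), with colour and shape for the array number and grey bars for the mean and SD of 3 arrays. Txnip on the array labelled calcitriol 3 (12.11) sits with the glucose arrays numbered 1 and 2 (12.29 and 12.22). Txnip on the array labelled glucose 3 (10.33) sits with the controls numbered 1 and 2 (10.48 and 10.39) and above control 3. On glucose 3, however, Nr4a1 (9.84) lies above glucose 1 and 2 (9.22 and 9.45), and Jun (7.41) lies nearer to them (6.90 and 6.99) than to the controls (8.09 to 8.21).

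The first comparison asked which transcripts differed after glucose in cells without vitamin D. The microRNA gene Mir23b had a log2 signal of 7.32 ± 0.15 (SD, n = 3) with glucose and 5.74 ± 0.07 (SD, n = 3) without, a difference of 1.58 (SE 0.28, adjusted p = 0.380 by limma). Mir7a-1 differed by 0.73 (SE 0.14), Uap1l1 by 0.56 (SE 0.11) and Gspt2 by -0.48 (SE 0.10), each with an adjusted p = 0.447. Txnip was 11.61 ± 1.11 with glucose and 10.25 ± 0.32 without (SD, n = 3), a difference of 1.36 with a 95% interval of 0.19 to 2.53. The insulin genes Ins1 and Ins2 differed by 0.01 (95% interval -0.10 to 0.12) and 0.03 (-0.07 to 0.13). Vdr, the vitamin D receptor gene, differed by -0.16 (-0.63 to 0.31), and Egr1, an immediate early transcription factor gene, by 0.49 (0.09 to 0.89). Limma called 0 of 9852 genes over the 18 arrays, and 599 had an unadjusted p under 0.05. With array weights the count was 1051, in a fit of these 2 groups alone it was 12, and it was 1 without the array labelled calcitriol 3 (Mir23b, 1.58) or without that labelled calcidiol with glucose 3 (Per1, 0.94).

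On the 12 arrays numbered 1 and 2, 104 genes passed, 87 higher and 17 lower after glucose, and 175 passed with the replicate number as a block (132 higher, 43 lower). Nr4a1, an orphan nuclear receptor gene induced within minutes of stimulation, rose by 2.84 (SE 0.24), Zfp36, encoding an mRNA-destabilising protein, by 2.25 (SE 0.09), the secreted peptide gene Prok2 by 2.25 (SE 0.19) and Txnip by 1.82 (SE 0.08). G0s2 rose by 1.92, Lcat by 1.86, Hbegf by 1.83 and Gadd45b by 1.77. Jun fell by 1.25 (SE 0.10), Id3 by 1.21, Arrdc3 by 0.95 and Myc by 0.74, and Srf, Prmt6, Tmem100 and Kcnj2 were also lower, at -0.73 to -0.63. Of the immediate early list, 36 genes were in the table and 23 passed the filter on low values. Of these 23 tested genes, 8 rose and 3 fell, and adjusted over the list alone 11 rose and 6 fell. Of 13 carbohydrate response genes, Txnip, Bhlhe40 (1.12) and Rgs16 (0.63) rose. Pfkfb3, which makes the activator of phosphofructokinase, rose by 1.16, and the beta-cell transcription factor gene Isl1 fell by 0.51.

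Over the 18 arrays, limma's camera test with its preset correlation placed 7 lists higher after glucose without vitamin D. The number of lists called was 4 with quantile normalisation. The calcium and cAMP responsive genes (median 0.17) and the circadian clock genes (median 0.04) passed, each with an adjusted p = 0.0484 with an estimated correlation. The immediate early genes had a median of 0.17 and an adjusted p = 0.0561 with an estimated correlation. Calls for the amino acid response, glycolysis, carbohydrate response and unfolded protein response genes were lost, with an adjusted p = 0.390, 0.70, 0.842 and 0.948 with an estimated correlation. With the replicate block the carbohydrate response genes had an adjusted p = 0.0777, and the cell cycle genes were lower at 0.0232, though without the block they had an adjusted p = 0.948 with an estimated correlation. Adjusted over the list alone, 10 immediate early genes were higher and 3 lower, 6 of the 18 calcium and cAMP responsive genes, 4 of the 14 clock genes and 1 of the 27 beta-cell identity genes were higher.

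After calcitriol, the genes with the smallest p for glucose over the 18 arrays were lower. The zinc finger genes Zbtb2 and Hivep2 differed by -0.39 (SE 0.07) and -0.32 (SE 0.06), each with an adjusted p = 0.377 by limma, and Hjurp and E2f3, which act in centromere assembly and the cell cycle, by -0.34 (SE 0.07) and -0.27 (SE 0.06), each at 0.395. Txnip differed by 1.26 (95% interval 0.09 to 2.43), Egr1 by 0.38 (-0.02 to 0.78), Vdr by -0.01 (-0.48 to 0.46), Ins1 by 0.06 (-0.05 to 0.17) and Ins2 by 0.05 (-0.05 to 0.14). Limma called 0 genes, with 972 at an unadjusted p under 0.05. The count was 373 with array weights, and 2 without the array labelled calcitriol 3, which were Mir23b (1.47) and Nr4a1 (3.49), and 1 without that labelled calcidiol with glucose 3 (Per1, 0.90), chosen after their values were seen. On the 12 arrays numbered 1 and 2, 186 genes passed, 129 higher and 57 lower, and 447 with the block, 223 higher and 224 lower. In them Nr4a1 rose by 3.61 (SE 0.24), Zfp36 by 2.70 (SE 0.09), the neuronal activity gene Npas4 by 2.62 (SE 0.42) and Txnip by 1.81 (SE 0.08), while Jun fell by 1.21, Arrdc3 by 1.12 and the melatonin receptor gene Mtnr1a by 0.88. Of 23 immediate early genes, 9 rose and 4 fell, against 13 and 5 adjusted over the list alone.

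Camera over the 18 arrays placed 7 lists away from the other genes after calcitriol, and the immediate early genes (median 0.32) held, with an adjusted p = 0.0120 with an estimated correlation. The circadian clock and the calcium and cAMP responsive genes were lost at an adjusted p = 0.0699 and 0.0718 with an estimated correlation. The amino acid response, unfolded protein response, glycolysis and cell cycle genes, the last lower with a median of -0.16, were lost at an adjusted p = 0.315, 0.398, 0.398 and 0.416 with an estimated correlation. Adjusted over the list alone, 10 immediate early genes were higher and 3 lower, 4 calcium and cAMP responsive and 3 clock genes were higher, and 1 p53 and apoptosis gene was lower.

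After calcidiol, among the genes with the smallest p, Setd6 differed by 0.41 (SE 0.10) with glucose, Fastkd5 by -0.34 (SE 0.09) and the acyl-CoA thioesterase gene Acot2 by 0.66 (SE 0.17), each with an adjusted p = 0.962 by limma over the 18 arrays. Txnip differed by 1.09 (95% interval -0.08 to 2.26), Egr1 by 0.18 (-0.22 to 0.58), Vdr by -0.13 (-0.60 to 0.34), Ins1 by -0.01 (-0.12 to 0.10) and Ins2 by -0.02 (-0.12 to 0.08). Limma called 0 genes, with 459 at an unadjusted p under 0.05, and 27 without the array labelled calcidiol with glucose 3. On the 12 arrays numbered 1 and 2, 133 genes passed, 102 higher and 31 lower, and 241 with the block, 163 higher and 78 lower. There Nr4a1 rose by 3.07 (SE 0.24), Zfp36 by 2.69 (SE 0.09), Nr4a2 by 2.26 (SE 0.16) and Txnip by 1.73 (SE 0.08), while Arrdc3 fell by 1.23, Jun by 1.17 and Prmt6 by 0.99. Of 23 immediate early genes, 7 rose and 4 fell, against 12 and 6 adjusted over the list alone. Over the 18 arrays camera placed 9 lists higher after calcidiol, and none held; the number was 4 with quantile normalisation, 5 without the filter, and 3 and 5 without the arrays numbered 1 and 3. The immediate early and the calcium and cAMP responsive genes had an adjusted p = 0.114 with an estimated correlation, the amino acid response genes 0.301, the clock and oxidative stress genes 0.309, the carbohydrate response genes 0.389, and the unfolded protein response, oxidative phosphorylation and ribosomal protein genes 0.688. Adjusted over the list alone, 6 immediate early, 4 calcium and cAMP responsive and 1 clock gene were higher and 3 immediate early genes lower. The clock genes had a median of -0.03 and a mean of 0.16, and with the block the calls for clock, unfolded protein response and oxidative phosphorylation genes ended, at an adjusted p = 0.186, 0.0610 and 0.0614.

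The glucose calls of the 12 arrays overlapped. The 3 pretreatments shared 69 genes that rose and 10 that fell. The first and second lists of genes that rose held 87 and 129 genes and shared 82, against 1.14 for independent lists. The lists were not independent, since 1 fit gave each gene the same variance in all of them. The 12 arrays were also chosen after seeing the data, so the overlap is a description only.

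The glucose effect was also averaged over the 3 pretreatments, setting 9 stimulated arrays against 9 unstimulated ones. This comparison was added after the 14 planned ones had each given 0 genes. Nr4a1 rose from 7.13 ± 1.17 to 9.61 ± 0.48 (SD, n = 9), by 2.49 (SE 0.39, adjusted p = 0.0129 by limma), and its mean was higher after glucose in each of the 3 pretreatments. Zfp36 rose by 1.83 (SE 0.36), Lcat, encoding the cholesterol-esterifying enzyme of plasma, by 1.53 (SE 0.33), Npas4 by 1.46 (SE 0.32), Nr4a2 by 1.44 (SE 0.23), the kinase gene Sik1 by 1.42 (SE 0.21), Gadd45b by 1.41 (SE 0.21) and Hbegf by 1.38 (SE 0.34). Jun fell by 0.88 (SE 0.13), Arrdc3 by 0.75 (SE 0.17), Id3 by 0.60, Prmt6 by 0.57, Myc by 0.53, Mtnr1a by 0.53, Myl7 by 0.52 and Srf by 0.46. Limma called 332 genes, 138 higher and 194 lower, with 1876 at an unadjusted p under 0.05, and 941 with the replicate block (290 higher, 651 lower). The balance of directions turned with the scaling, to 168 higher and 137 lower after quantile normalisation and 175 higher and 137 lower after median centring of each array. The count was 2 without moderation of the variances, 201 with the stricter filter and 1171 with array weights. With the 12 arrays numbered 1 and 2 it was 979 (370 higher, 609 lower), with the block 1564 (504 higher, 1060 lower), and 137 of the 138 higher and 182 of the 194 lower genes were among the 979. Without the arrays numbered 1, or without those numbered 2, it was 0. Single arrays also moved it. It was 94 and 85 without calcitriol with glucose 1 and 2, 36, 30 and 529 without calcitriol 1, 2 and 3, and 81 and 37 without glucose 1 and 2. It was 66 and 157 without calcidiol 1 and 2, 58, 78 and 806 without calcidiol with glucose 1, 2 and 3, and 35, 68 and 116 without control 1, 2 and 3.

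The list counts of the averaged comparison come from the fit of all arrays. Of 23 tested immediate early genes, 9 rose, 5 fell (Jun, Myc, Srf, Klf6 and Ier5) and 9 did not pass. Adjusted over the list alone 14 rose and 6 fell. With only the arrays numbered 1 and 2, 17 immediate early genes passed over all tested genes. Of 18 calcium and cAMP responsive genes 5 rose, among them Per1 (0.84, SE 0.11), against 9 adjusted over the list alone. Of 14 circadian clock genes 4 rose, namely Per1, Bhlhe40 (0.75), Bhlhe41 and Nfil3 (0.54), and the same number adjusted over the list alone. These 3 lists held in camera, with an adjusted p = 0.0281, 0.0386 and 0.0494 with an estimated correlation. They share members, so the 3 calls are not independent. Of 13 carbohydrate response genes, Txnip (1.24, SE 0.32), Bhlhe40 and Rgs16 (0.50) rose, 3 also adjusted over the list alone. Of 19 glycolysis genes, Ldhb (0.64) and Pdk1 (0.27) rose, against 3 higher and 1 lower adjusted over the list alone. Of 25 amino acid response genes, the amino acid transporter gene Slc7a5 rose (0.26), against 4 adjusted over the list alone. Camera's calls for the carbohydrate response, glycolysis and amino acid response genes were lost, at an adjusted p = 0.508, 0.508 and 0.156 with an estimated correlation.

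Of 27 beta-cell identity and hormone genes, Foxa2 rose (0.23) and Isl1 (-0.39), Insm1 (-0.30) and Neurod1 fell, against 1 higher and 8 lower adjusted over the list alone. Ins1 and Ins2 differed by 0.02 (95% interval -0.04 to 0.08) and 0.02 (-0.04 to 0.07). Of 38 secretion and channel genes, the vesicle gene Vamp2 rose (0.20) and Kcnj11, the pore of the ATP-sensitive potassium channel, fell (-0.23), the same counts as adjusted over the list alone. Of 16 p53 and apoptosis genes Plk3 rose (0.87), against 4 higher and 2 lower adjusted over the list alone. Of 23 sterol synthesis genes Pmvk rose (0.32), against 1 higher and 1 lower adjusted over the list alone, and of 35 cell cycle genes Ccne1 fell (-0.26; its call ended under both scalings), against 0 adjusted over the list alone. Of 10 inflammatory genes 0 passed and 1 did adjusted over the list alone. With all arrays in the fit, no member passed among 26 unfolded protein response, 41 oxidative phosphorylation, 17 oxidative stress and 45 ribosomal protein genes. Nor did any among 8 vitamin D response, 8 vitamin D metabolism and 6 other cell type genes. Both hold by limma over all genes and adjusted over the list alone. On the arrays numbered 1 and 2 the calls of list members can differ, and they are not given here for these lists. Camera's calls for the unfolded protein response genes (higher, median 0.02) and cell cycle genes (lower, median -0.08) were lost, at an adjusted p = 0.575 and 0.668 with an estimated correlation. Vdr differed by -0.10 (-0.37 to 0.17) and Egr1 by 0.35 (0.12 to 0.58, adjusted p = 0.0869 by limma). With the replicate block Egr1 passed, at an adjusted p = 0.0450 by limma.

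**Figure D2:**
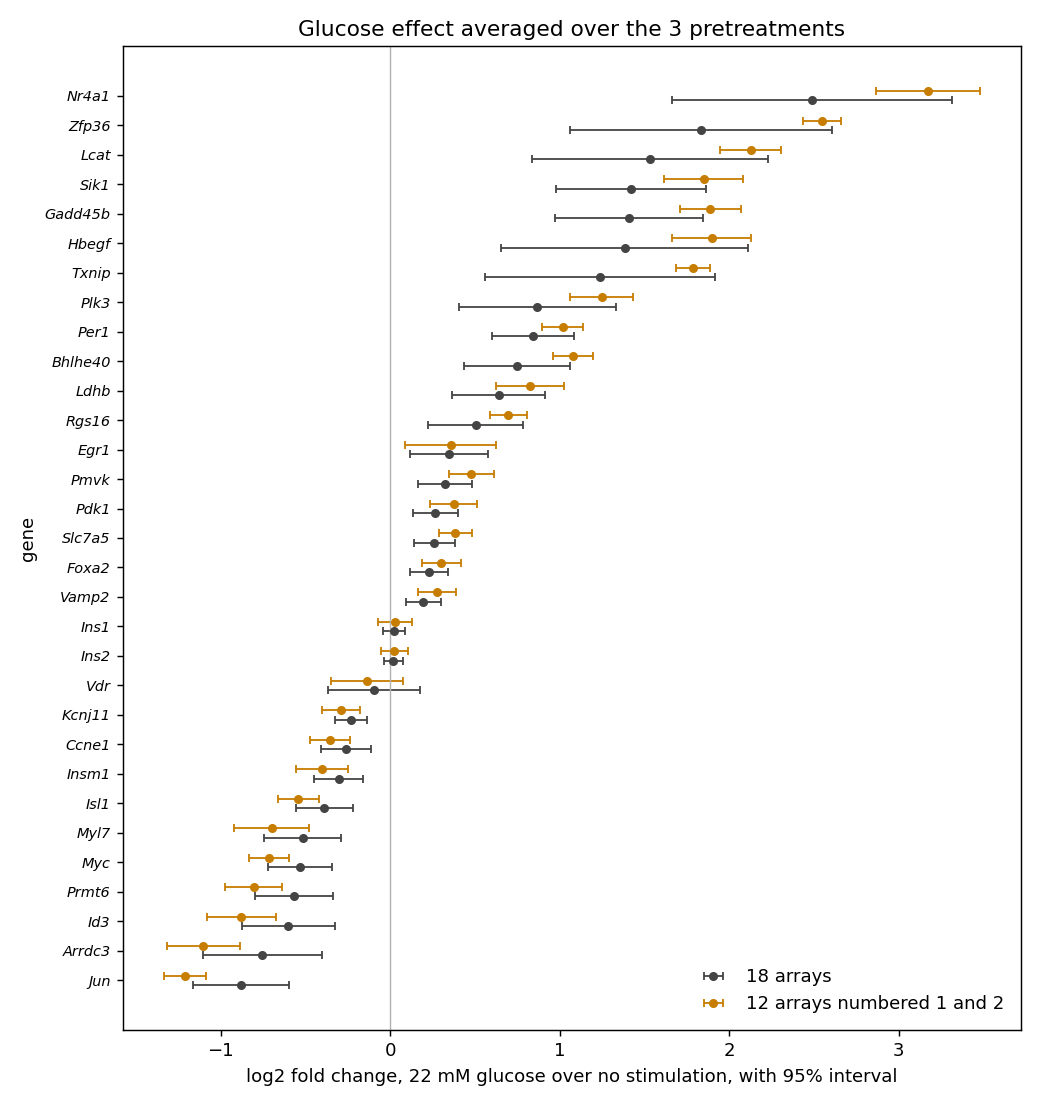
Log2 fold change with its 95% interval (horizontal axis) of named genes (vertical axis) for 22 mM glucose over no stimulation, averaged over the 3 pretreatments, from all 18 arrays (grey) and from the 12 arrays numbered 1 and 2 (orange). Nr4a1 stood at 2.49 and 3.17, and Jun at -0.88 and -1.21.

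Calcitriol was then set against no vitamin D. Without glucose, Casr was 7.36 and 7.27 on the arrays labelled calcitriol 1 and 2 and 6.49 on that labelled calcitriol 3, against 6.29, 6.19 and 6.43 in the controls. Over the 18 arrays the genes with the smallest p included Dact1 (0.24, SE 0.07), Nelfb (-0.18, SE 0.05), Gspt2 (-0.32, SE 0.10) and Tmem237 (-0.18, SE 0.06), and with glucose Arv1 (0.26, SE 0.07), Hjurp (-0.22, SE 0.07) and Pik3c2a (-0.21, SE 0.07). Vdr differed by -0.03 (95% interval -0.50 to 0.44) without glucose and by 0.11 (-0.36 to 0.58) with it, Ins1 by -0.03 (-0.14 to 0.08) and 0.02 (-0.09 to 0.13), Ins2 by 0.0010 (-0.10 to 0.10) and 0.02 (-0.08 to 0.12), Txnip by 0.76 (-0.41 to 1.93) and 0.66 (-0.51 to 1.83), against 0.03 (-0.14 to 0.21) and 0.02 (-0.15 to 0.19) on the 12 arrays numbered 1 and 2, and Egr1 by 0.09 (-0.32 to 0.49) and -0.02 (-0.42 to 0.38). Averaged over glucose states, the smallest p belonged to Polr2i (-0.18, SE 0.05), Med20, Mst4 and Mcee. Limma called 0 genes in each of these 3 comparisons, with 77, 38 and 60 at an unadjusted p under 0.05.

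Among the 12 arrays numbered 1 and 2, Casr rose with calcitriol by 1.08 (SE 0.09, adjusted p = 0.00235 by limma) without glucose and by 1.02 (SE 0.09, adjusted p = 0.00396) with it, and Adam23, encoding a membrane protein of the disintegrin family, by 1.12 (SE 0.14) and 1.17 (SE 0.14). These 2 genes were the only calls in either state. The 12 arrays were chosen after the data were seen, and Casr is among the genes that set the arrays numbered 3 apart. These p-values do not allow for that choice. On the arrays numbered 3, Casr was 6.49 with calcitriol and 6.43 in the control, and with glucose 6.45 and 6.33. Averaged over glucose states, the cell adhesion gene Nrcam also rose (0.65, SE 0.07, adjusted p = 0.0104), making 3 genes, and 9 passed with the block. None of the 8 tested vitamin D response or 8 tested vitamin D metabolism genes passed in any vitamin D comparison over the 18 arrays, by limma over all genes or adjusted over the list alone. On the 12 arrays, 1 response gene was higher in the average adjusted over the list alone. The full lists held 22 and 17 genes, and Cyp24a1, Trpv6, S100g, Thbd and Cd14 were among those not tested. Camera placed the sterol synthesis genes lower without glucose (median -0.05), with an adjusted p = 0.914 with an estimated correlation. It called 3, 0 and 6 lists there without the arrays numbered 1, 2 and 3. With glucose it placed the cell cycle genes lower (median -0.11) and the immediate early, other cell type, unfolded protein response and amino acid response genes higher, and all were lost, at an adjusted p = 0.807, 0.0690, 0.0741, 0.885 and 0.807 with an estimated correlation. In the average over glucose states the cell cycle and sterol synthesis genes were lower and the immediate early, amino acid response and other cell type genes higher, with an adjusted p = 0.709, 0.709, 0.217, 0.709 and 0.217 with an estimated correlation, and the other cell type call also ended with the block, at 0.0502.

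Calcidiol was set against no vitamin D in the same way. Vdr was 7.99 ± 0.46 (SD, n = 3) with calcidiol and 7.55 ± 0.01 without, a difference of 0.44 (95% interval -0.03 to 0.91), and with glucose the difference was 0.47 (0.0029 to 0.94). The calcidiol arrays 1 to 3 were at 7.5, 8.05 and 8.41 without glucose and at 7.37, 7.73 and 8.49 with it. With only the arrays numbered 1 and 2 the differences were 0.23 (-0.14 to 0.59) and 0.16 (-0.21 to 0.53). Without glucose the smallest p belonged to Gpsm2 (-0.29, SE 0.06), Atp5i (-0.28), Nt5c3a (-0.28) and Tbcb (-0.40), and with glucose to Wdyhv1 (-0.34, SE 0.09), Tshz3 (0.31), the replication gene Cdc45 (-0.31) and Duxbl1 (-0.31). Ins1 differed by 0.04 (-0.07 to 0.15) without glucose and 0.02 (-0.09 to 0.13) with it, Ins2 by 0.04 (-0.06 to 0.14) and -0.0058 (-0.10 to 0.09), Txnip by 0.21 (-0.97 to 1.38) and -0.07 (-1.24 to 1.10), against 0.03 (-0.14 to 0.21) and -0.05 (-0.23 to 0.12) for the arrays numbered 1 and 2, and Egr1 by 0.18 (-0.22 to 0.58) and -0.13 (-0.53 to 0.27). Limma called 0 genes without glucose, with glucose and averaged over glucose states, with 238, 259 and 660 at an unadjusted p under 0.05. In the average, Wdyhv1, Aaas, Duxbl1 and Mst4 had the smallest p (adjusted p = 0.722), and without the array labelled calcidiol 1 Cdc45 passed (-0.30), named after its values were seen. On the 12 arrays numbered 1 and 2 the counts were also 0, with 266, 353 and 549 at an unadjusted p under 0.05. Over the 18 arrays camera placed the sterol synthesis genes (median -0.12) and cell cycle genes (median -0.11) lower without glucose, both lost at an adjusted p = 0.658 and 0.728 with an estimated correlation. With glucose no list passed in the main fit, and 0 to 3 did under the alternatives. Both lists passed with the replicate block, at an adjusted p = 0.0182 by camera, and without the block each had an adjusted p = 0.996 with an estimated correlation. In the average both were lower again (medians -0.11 and -0.10), with an adjusted p = 0.596 and 0.919 with an estimated correlation, 1 sterol synthesis gene was lower adjusted over the list alone, and the other cell type genes passed with the block, at 0.0384, against an adjusted p = 0.393 with an estimated correlation and no block.

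**Figure D3:**
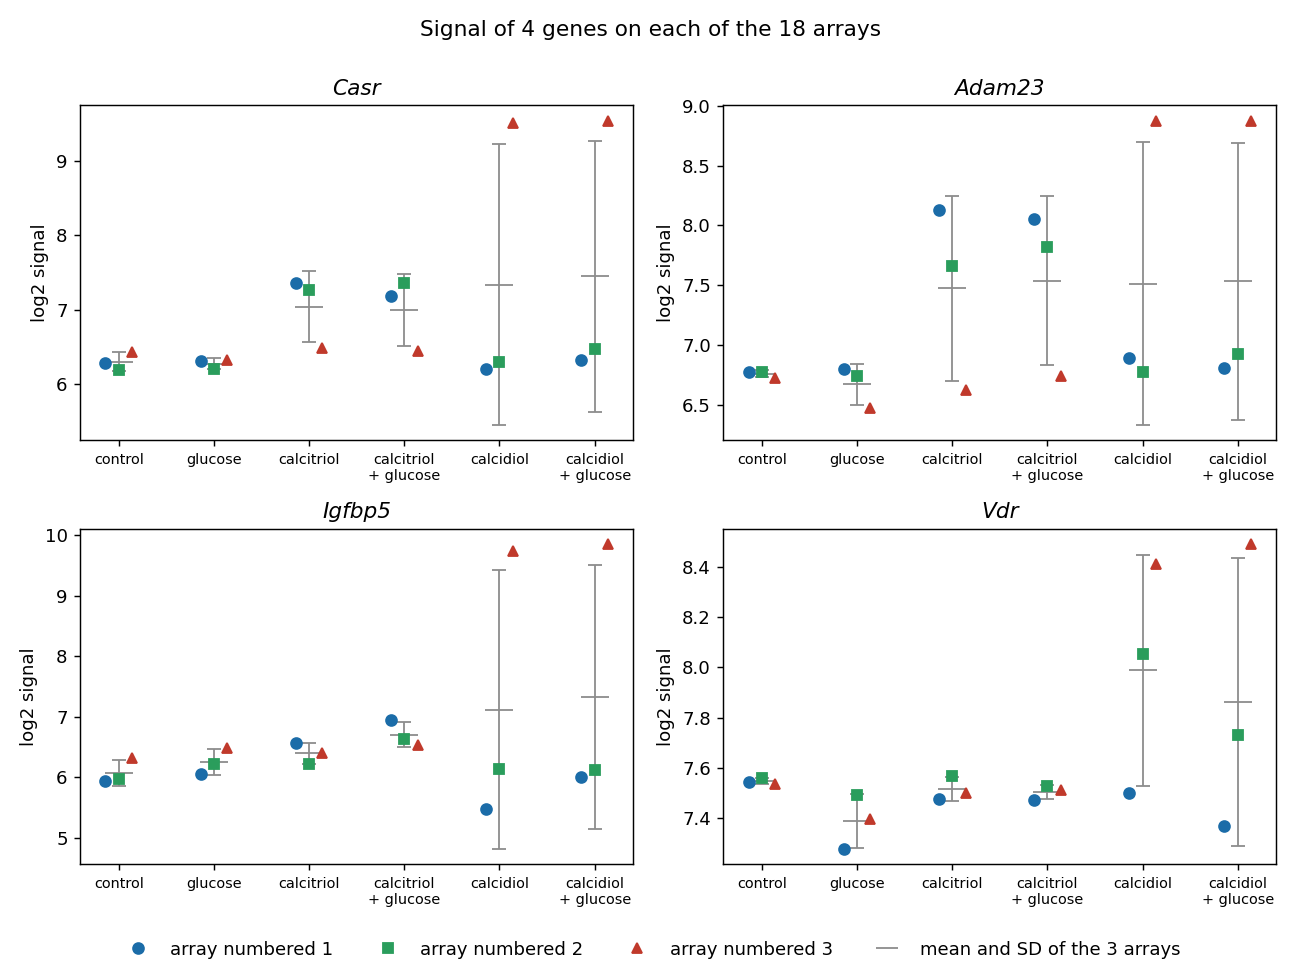
Log2 signal (vertical axes) of Casr, Adam23, Igfbp5 and Vdr on each of the 18 arrays, by group (horizontal axes), with colour and shape for the array number and grey bars for the mean and SD of 3 arrays. Casr lies at 9.52 and 9.55 on the calcidiol arrays numbered 3, and at 7.18 to 7.36 on the calcitriol arrays numbered 1 and 2; Igfbp5 was chosen after its values were seen.

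Calcitriol and calcidiol, which differ by the hydroxyl group at carbon 1, were compared at the same 10 nM and 72 h. Over the 18 arrays Vdr was lower with calcitriol by a difference of -0.47 (95% interval -0.95 to -0.0048) without glucose and -0.36 (-0.83 to 0.11) with it, with an adjusted p = 1.00 and 0.999 by limma. With only the arrays numbered 1 and 2 these differences were -0.26 (-0.62 to 0.11) and -0.05 (-0.42 to 0.32), so the calcidiol arrays numbered 3 carried much of them. The differences were -0.07 (-0.18 to 0.04) and -0.0060 (-0.12 to 0.10) for Ins1, -0.04 (-0.14 to 0.06) and 0.02 (-0.07 to 0.12) for Ins2, 0.56 (-0.61 to 1.73) and 0.73 (-0.44 to 1.90) for Txnip, which was 0.00025 (-0.17 to 0.17) and 0.07 (-0.10 to 0.25) with only the arrays numbered 1 and 2, and -0.09 (-0.49 to 0.31) and 0.11 (-0.29 to 0.51) for Egr1. The smallest p without glucose belonged to Agps (0.19), Drg1 (0.23), Snx6 (0.19) and Ubxn2b (0.19), and with glucose to Daxx (0.23), Rps6ka4 (0.23), Arrb2 (0.37) and Arv1 (0.26). In the average over glucose states they were Daxx (0.15), Rpo1-3 (-0.16), the apoptosis gene Bax (0.20) and Hsph1 (-0.28). Limma called 0 genes in each, with 96, 309 and 291 at an unadjusted p under 0.05. On the 12 arrays numbered 1 and 2, Casr was higher with calcitriol than with calcidiol by 1.06 (95% interval 0.86 to 1.27, adjusted p = 0.00260) without glucose and 0.87 (0.67 to 1.08, adjusted p = 0.0178) with it, and Adam23 by 1.07 (0.77 to 1.38, adjusted p = 0.0487) with glucose. On the same 12 arrays with the block, 2 genes passed without glucose, and 3 with it, 2 higher and 1 lower. Averaged over glucose states Casr, Adam23 and Nrcam passed there, and 21 genes with the block. On the arrays numbered 3 the order was the opposite, with Casr at 6.49 and 6.45 for calcitriol and 9.52 and 9.55 for calcidiol. The p-values of the 12 arrays do not allow for leaving these arrays out after the data were seen. Camera placed the cell cycle (median 0.11), sterol synthesis and oxidative phosphorylation genes higher with calcitriol without glucose, and each was lost at an adjusted p = 0.743 with an estimated correlation. With the block the oxidative phosphorylation call ended, at an adjusted p = 0.0557, and the carbohydrate response genes passed, at 0.0329, against an adjusted p = 0.743 with an estimated correlation and no block. In the average no list passed in the main fit, and 0 to 3 did under the alternatives. With the block the sterol synthesis genes were higher at an adjusted p = 0.0317 by camera, against an adjusted p = 0.748 with an estimated correlation and no block. Adjusted over the list alone, 1 p53 and apoptosis gene was higher.

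The difference in the glucose effect between pretreatments was tested as an interaction. For calcitriol the genes with the smallest p included Tbkbp1 (0.32, SE 0.09), Hjurp (-0.31, SE 0.10) and MAST1 (0.26, SE 0.09), and Txnip gave -0.10 (95% interval -1.76 to 1.56). For calcidiol they included Tshz3 (0.35, SE 0.11), Gpsm2 (0.28, SE 0.09) and Mir7a-1 (-0.60, SE 0.20), and Txnip gave -0.27 (-1.93 to 1.38). Limma called 0 genes in either, with 66 and 32 at an unadjusted p under 0.05, and 0 on the 12 arrays numbered 1 and 2, with 144 and 138.

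Across the 9852 genes, which are not independent replicates, the calcitriol and calcidiol effects without glucose correlated at 0.579, with a covariance of 0.00462. In simulations of unchanged groups with the same controls the means were 0.501 and 0.00789 with independent arrays, and 0.562 and 0.00598 with arrays of the same number correlated as observed, a simulation chosen after seeing the data. With glucose the correlation was 0.403 and the covariance 0.00337, against 0.498 and 0.00787 with independent arrays and 0.367 and 0.00318 with correlated ones. With 3 controls no split into parts of 2 arrays was possible, so part of any excess may come from the shared controls. The calcitriol effects with and without glucose correlated at 0.172 (covariance 0.00115), against -0.000805 simulated with independent arrays but 0.112 (covariance 0.000994) with correlated ones. The calcidiol effects with and without glucose correlated at 0.581 (covariance 0.0058), against 0.00375 with independent arrays and 0.388 (covariance 0.00404) with correlated ones. In that order, the simulated correlations with correlated arrays spanned 0.520 to 0.596, 0.304 to 0.415, 0.038 to 0.180 and 0.314 to 0.441. Only the last observed correlation lay outside its range, which treats genes as independent. Genes of the same sign made up 67.7%, 62.3%, 49.5% and 68.0%. The simulated spans with correlated arrays were 67.9% to 69.9%, 61.0% to 63.1%, 52.1% to 54.4% and 61.6% to 63.7%.

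Single arrays moved each of these correlations. The first was 0.249 without calcidiol 3, and the second was 0.224 without calcitriol with glucose 2 and 0.197 without calcidiol with glucose 2. That of the calcitriol effects with and without glucose was 0.0713, 0.0608, 0.0403 and 0.0709 without calcitriol with glucose 1, calcitriol 3, glucose 3 and control 1. That of the calcidiol effects was 0.281 without calcidiol 3 and 0.228 without calcidiol with glucose 3. Among the 12 arrays numbered 1 and 2 the 4 correlations were 0.373, 0.342, 0.142 and 0.276.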

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

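The tests of the arrays numbered 3, of shared cultures and of other splits of the arrays were chosen only after the results were seen, and the list tests before the data were examined.

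The difference between the glucose effects with and without calcitriol passed camera's preset test for 3 lists, against 0, 1 and 4 lists without the arrays numbered 1, 2 and 3. The immediate early genes (median 0.12, adjusted p = 0.0108) and the unfolded protein response genes (median 0.04, adjusted p = 0.0108) were higher, and had an adjusted p = 0.546 and 0.956 with an estimated correlation. The cell cycle genes were lower (median -0.10, adjusted p = 0.00153), with an adjusted p = 0.956 with an estimated correlation.

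The glucose response and the labels disagreed among the arrays numbered 3. Over the 979 genes called on the arrays numbered 1 and 2, on a scale with 0 at the unstimulated and 1 at the stimulated mean of those same arrays, the array labelled calcitriol 3 scored 0.548 (SE over genes 0.024) against -0.03 to 0.04 for the unstimulated arrays numbered 1 and 2, which set the 0, and 0.737 over 17 immediate early and 0.881 over 3 carbohydrate response genes, so a glucose-stimulated sample is a candidate explanation, though 0.548 lay just above a bound of 0.5 set after gene values had been seen and below the 0.729 of calcitriol with glucose 3 and the 0.889 to 1.10 of the stimulated arrays numbered 1 and 2. The array labelled glucose 3 scored 0.650 (SE 0.149) and that labelled calcidiol with glucose 3 scored 0.333 (SE 0.120) over the immediate early genes, 0.02 and -0.06 over the carbohydrate response genes, and 0.329 and 0.123 over all 979. Over the carbohydrate response genes control 3 scored -0.21 and calcidiol 3 scored 0.02. Over the immediate early genes the unstimulated arrays numbered 1 and 2 lay between -0.06 and 0.05, and control 3 scored -0.00055 (SE 0.024). Glucose 3 lay above all of these, which goes against an unstimulated sample there. Its 0.02 over the 3 carbohydrate response genes goes the other way. Calcidiol 3, unstimulated by its label, scored 0.411 (SE 0.124) over the immediate early genes and 0.144 over all 979. Whether glucose 3 or calcidiol with glucose 3 held an unstimulated sample therefore cannot be told. Calcidiol 3 and calcidiol with glucose 3 were the closest of all pairs of arrays, with an SD of their difference of 0.0767, against 0.110 for the next pair. Calcitriol 3 and calcitriol with glucose 3 were at 0.116. Such closeness does not tell whether a pair was stimulated. Poorer arrays are argued against by the spread of deviations, at most 0.160 on an array numbered 3 and 0.245 elsewhere, while mixed samples, another timing of stimulation or another culture state stay open, and no biological explanation was tested.

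Genes higher after calcitriol on the arrays numbered 1 and 2 were high on the calcidiol arrays numbered 3. Over the 30 such genes with the smallest p, of which 3 had passed, scaled to 1 at the calcitriol mean of the arrays that chose them, the calcidiol arrays numbered 3 averaged 2.54 and the calcitriol arrays numbered 3 averaged 0.132, near the top of the range of the arrays without vitamin D (-0.07 to 0.134) and below the calcitriol arrays numbered 1 and 2 (0.781 to 1.23). Calcidiol acting more strongly while calcitriol acted as on the other arrays is therefore argued against by the 0.132. An exchange of the 2 labels is a candidate explanation, but the 2.54 exceeds any calcitriol array, so it would also need a larger response. Of 42 genes over 1 log2 unit apart between the calcidiol arrays and the arrays without vitamin D numbered 3, 100% had a calcitriol effect of the same sign on the other arrays (39.8% of other genes were positive), so an enlarged calcitriol response there is also a candidate explanation, and what enlarged it, such as dose or culture state, stays open.

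Arrays that shared a pretreatment and a number deviated together. Their 9 pairs correlated at 0.474 on average, against 0.319 for the 36 pairs that shared only the number (exact one-sided permutation p = 0.00463 over 216 renumberings, and also over 216 exchanges of the pretreatments within a number, the smallest either can give). Without the calcidiol groups the 6 remaining pairs averaged 0.377 (SE 0.061), against 0.377 for the 12 that shared only the number and 0.319 for the 6 of those in opposite glucose states. A culture per pretreatment and number, split over both glucose states, therefore cannot be told apart from shared days or shared handling, since the excess over pairs sharing only the number was within the SE without calcidiol.

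Other splits were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and since the real count was 0 in all 9 such comparisons, 10 of 10 splits gave as many and decide nothing. The highest other split gave 134 for the glucose effect after calcidiol and 0 in the other 8. That split joined calcidiol 1, calcidiol 3 and calcidiol with glucose 3 and points to a structure of the samples, and the splits that part all 3 pairs gave 0. For the interactions and the 3 averages of vitamin D effects the real count was again 0, so 100 of 100 drawn splits gave as many by construction and again decide nothing. The highest others were 32, 149, 0, 305 and 359, and those above 0 also point to such a structure. For the averaged glucose effect, 1 of 100 splits, the real one, gave 332 genes and the highest other gave 12. Among 100 of the 256 splits that, like the real one, part all 9 pairs of the same pretreatment and number, again only the real one did, and the highest other, which exchanged the calcitriol pair numbered 3, gave 2. No other drawn split reached that count. The splits cannot exclude chance differences between cultures, since the labels do not say that the samples came from separate cultures. The comparison itself was also chosen after the planned ones had given 0.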

How the results depend on the processing

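The averaged glucose comparison with all its alternatives, and leaving out all arrays of 1 number, were chosen only after the data were seen. Of the gene counts under alternatives other than left-out arrays, 172 stayed within 1.5 times and 7 did not. Most of the 172 were planned comparisons whose count of 0 stayed 0, so they say little about robustness. With array weights the count was 1051 for glucose without vitamin D, 373 for glucose after calcitriol and 1171 for the averaged glucose effect, where the weights ran from 0.342 to 8.83 and their estimation gave a convergence warning. With the compared groups alone, the first was 12. For the averaged glucose effect the count was 201 with the stricter filter, which tests fewer genes, 2 without moderation of variances, and 941 with the replicate block. The block moved no other count of genes over the 18 arrays, and no list call beyond those named with the results. The list calls over the 14 comparisons numbered 44, and 3 with an estimated correlation. With the replicate block, no filter or a stricter one, the values of the series matrix, quantile normalisation, an intensity trend or a left-out number, the lists called ran from 4 to 8 for glucose without vitamin D, 6 to 9 after calcitriol and 3 to 9 after calcidiol, from 0 to 6 and 3 to 8 for calcitriol without and with glucose, 2 to 5 and 0 to 3 for calcidiol, and 2 to 4 and 0 to 6 for calcitriol against calcidiol. They ran from 0 to 4 and 0 to 3 for the calcitriol and calcidiol interactions, and for the averages from 4 to 8 for calcitriol, 0 to 5 for calcidiol and 0 to 3 between them. The cause of the other shifts was not tested.

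Leaving out arrays gave from 0 to 104 genes for glucose without vitamin D, 0 to 186 after calcitriol, 0 to 133 after calcidiol and 0 to 979 for the averaged glucose effect. The range was 0 to 2 for calcitriol without and with glucose, 0 to 3 for its average, 0 to 1 for the average of calcidiol, and for calcitriol against calcidiol 0 to 1 without glucose, 0 to 2 with it and 0 to 3 averaged. All of the upper ends came from leaving out the arrays numbered 3, except that of the calcidiol average, which came from leaving out calcidiol 1.

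Of 1729 values of named genes under alternatives, 1647 kept direction and call, 43 lost the call, 32 of them without moderation, 13 gained it, and 26 changed sign or came to 0, none of them larger than 0.124 in size. The cause was not tested. With quantile normalisation Ins2 was 0 for glucose without vitamin D, calcitriol without glucose, calcidiol without glucose and calcitriol against calcidiol without glucose, -0.013 and 0.025 for the averages of calcidiol and of calcitriol against calcidiol, and -0.000455 for averaged glucose, Vdr was 0.014 for glucose after calcitriol, and Ins1 0.0098 for glucose after calcidiol and 0.0082 for the calcidiol interaction. With median centring Vdr was 0.015 for glucose after calcitriol, Ins1 0.012 for glucose after calcidiol and 0.0026 for the calcitriol average, Ins2 0.00091 for glucose after calcidiol and 0.016 for calcidiol with glucose, and Egr1 -0.00069 for calcitriol against calcidiol averaged. With array weights Ins1 was 0.0012 for glucose after calcidiol, Vdr 0.0068 for calcitriol without glucose and -0.057 for the calcidiol interaction, Ins2 0.023 for calcidiol with glucose, and Txnip -0.086 for the calcidiol average. There Egr1 was -0.0078 for calcitriol without glucose, 0.071 for calcidiol with glucose, -0.12 for calcitriol against calcidiol with glucose, -0.026 for the calcitriol average and -0.12 for calcitriol against calcidiol averaged. The scalings moved the median of all genes by at most 0.026.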

Other observations

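The genes named here, and the test of unnamed probe sets, were chosen after the values were seen. The calcidiol arrays numbered 3 also carried the lowest signal of the glucagon gene Gcg, at 10.27 and 10.20 without and with glucose, where the other 16 arrays lay between 11.32 and 12.16. The genes furthest apart between those 2 arrays and the arrays without vitamin D numbered 3 were Igfbp5 (3.39), which binds insulin-like growth factors, Casr (3.15), the sodium channel subunit gene Scnn1g (2.80), Lppr1 (2.53), Adam23 (2.27) and Tnfrsf11b (2.24), which encodes osteoprotegerin. Igfbp5 was also among the tested genes of the vitamin D response list.

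Other genes differed between numbers within a group. Tgfb2 was 5.95 on calcidiol 1 and 9.23 on calcidiol 2, and Ptges, a prostaglandin E synthase gene, was 6.35 and 9.06, while on the controls they spanned 7.02 to 8.02 and 7.67 to 7.88. Fos, below the filter, was 4.92 to 5.57 on the controls and 6.39 to 7.54 on the glucose arrays, highest on glucose 3. It was 5.22 and 5.24 on calcitriol 1 and 2 but 7.05 on calcitriol 3, and 5.28 and 5.27 on calcidiol 1 and 2 but 6.69 on calcidiol 3. The arrays with glucose after calcitriol spanned 6.56 to 7.33 and those after calcidiol 6.35 to 7.21.

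The 12197 probe sets of the series matrix outside the attached table, unnamed here, were tested for the averaged glucose effect. By limma 0 passed, with 753 at an unadjusted p under 0.05, and 19 passed on the 12 arrays numbered 1 and 2.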
